A study of Mus musculus with 8 samples.

How the data were processed

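Poly(A) RNA from 8 whole mouse pancreases (4 controls, 4 labelled as lacking Gata6 in the pancreas; strain given as mixed) had been made into TruSeq libraries with 8 cycles of PCR and sequenced on a Genome Analyzer IIx, per the labels' protocols, from RNA with integrity numbers of 7.1 to 8.8. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.4, Bowtie, Cufflinks 2.0.1 and the mouse builds mm9 and NCBIM37. Read length, strand, the gene model release and the scaling option are not given in the sources used here. Each sample had 1 table of gene FPKM with interval bounds and a status, deposited by the authors as Cufflinks wrote it, with 36448 entries for 36432 Ensembl gene IDs. The 14 IDs found on more than 1 entry were summed.

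The deposited FPKM values summed to between 2.34e+10 and 1.86e+11 per sample, so they were not scaled to a fixed library size. The denominators implied by the intervals were 1.97 to 2.25 times the upper quartile of the implied fragments per gene, as a scaling to the upper quartile would give. All values were divided by 1 constant, 100000, a choice made after the files were seen, so that the pseudocount and the expression minimum fixed beforehand apply to values of the usual size; the result is called rescaled FPKM. A value of 1 rescaled FPKM is therefore no fixed number of transcripts. The tables used here hold no counts, and no count test was run. Fragment numbers were implied from the interval widths, which give 5325492 to 8957747 per sample without the genes that lack an estimate. In rescaled units 1 fragment was worth a median of 0.0365 to 0.0959 per sample in genes that implied a single fragment, and its worth differs by gene. Only 36.9% to 43.0% of the low genes with 1 transcript gave whole fragments within 0.02, so the implied numbers served to describe depth and, as an alternative, to rescale the samples. For some genes they are no fragment count, such as AL645948.1, which implied as few as 3.3e-16. They do not cover variation between animals.

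Cufflinks gave 8 genes (Pnlip, Amy2b, 5 Amy2a genes and Ctrb1) the status HIDATA in at least 1 sample and lists them at 0 there, in pancreas where they are abundant. These zeros are missing estimates, and the 8 genes were left out of the tests, a choice also made after the files were seen. They numbered 6 to 8 in the controls and 0 to 6 in the labelled libraries. The implied fragment totals, and the scaling to them, thus miss unequal numbers of abundant genes. Coordinates are those of the files, on mm9, with the start raised by 1 to count from 1. In 6996 of 8317 genes with a single exon the end minus the start in the file equalled the annotated length, against 53 where it was 1 short. GENCODE M21, which is on another build, was used through gene IDs only, for biotypes and lengths, and 31818 IDs matched. Cufflinks assigns shared fragments by likelihood, so values of paralogs, of overlapping genes and of antisense genes are uncertain.

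Genes with a mean of at least 1 rescaled FPKM over the 8 samples were tested, 11860 in all, with limma 3.58.1 in R 4.3.3 on log2(rescaled FPKM + 1), without further scaling and with an intensity trend, two-sided, and p-values were Benjamini-Hochberg adjusted over all genes tested at a threshold of 0.05. Positive log2 fold changes are higher in the libraries labelled Gata6-deleted. For Gata6 an exact two-sided permutation test of the 8 values was added. Of 31 gene lists written from textbook knowledge, 27 had at least 4 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists, with camera at an estimated correlation and fry as alternatives. Each list also had its members adjusted over the list alone. Lists overlap in a few genes, and whole pancreas holds all the cell types listed apart from possible neighbouring tissue. The genes named in the text were fixed by a rule: Gata6; the 12 largest rises and 12 largest falls among genes that passed with groups that did not overlap, leaving out predicted genes, small RNAs and immunoglobulin segments; up to 4 passing members of each list or, where none passed, the 2 of highest mean; and a set of acinar, duct and islet genes with Xist. The design, lists, this rule and the first set of alternatives were fixed before the data were examined.

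The test was tried on simulated data with 50 changed genes per size among 11860. With the spread of the controls it recovered 18% of true log2 changes of 0.5, 66% of 1, 88% of 2 and 98% of 3. With the residual spread of the real comparison it recovered 4%, 46%, 82% and 84%. Among unchanged genes it called 6 and 9. The changed genes were drawn from those with a mean log2 level above 2 in the controls, so lower genes were not covered. Each gene varied independently there, unlike in tissue. The alternatives were 2 other pseudocounts (0.1 and 5), no expression minimum or one of 5, median-ratio, quantile and equal-sum scalings, limma without trend, with robust variances or with sample weights, genes of good status only, Xist as a covariate, the BKD titles alone and each sample left out in turn. Added after seeing the data were the deposited scale, the HIDATA genes kept at 0, protein-coding genes only, the set without labelled libraries 1 and 3, the ASK and BSH titles alone, the title prefix as a covariate and a scaling to the implied fragment totals. The labels say that the samples came from separate mice only by listing 4 of each kind, and the replicate numbers follow the order of the records. Figures and further tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.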

Results

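Whole pancreases of 8 mice aged 6 to 8 weeks were profiled by sequencing poly(A) RNA, 4 from controls and 4 from mice labelled as lacking Gata6 in the pancreas. All 8 mice carried a Cre recombinase gene inserted at Ptf1a, a gene active in pancreatic progenitors and acinar cells. The mice of the second group also carried floxed Gata6 alleles. The comparison asks how expression in the adult pancreas differs when Gata6, a zinc finger transcription factor of the developing and adult pancreas, has been targeted there. The 4 libraries of the second group are called labelled libraries 1 to 4, because the level of Gata6 itself did not check their label. Expression is given as rescaled FPKM, the deposited FPKM divided by 100000, since the deposited values were not scaled to a fixed library size. Fragment numbers implied by the deposited intervals, without the genes that lack an estimate, summed to between 6731314 and 7917966 in the controls. They summed to 5325492, 5803908, 8957747 and 6667921 in labelled libraries 1 to 4. Genes with a value above 0 numbered 18345 to 19729 in the controls and 23024, 20193, 22715 and 19684 in labelled libraries 1 to 4. Control 1 and labelled libraries 1, 3 and 4 had titles starting with BKD and expressed Y-linked genes (Eif2s3y at 5.34, 13.7, 7.66 and 7.66). Controls 2 to 4 (titles starting with ASK) and labelled library 2 (BSH) expressed Xist at 24.5, 17.3, 26.1 and 32.0. Title prefix and sex were thus partly confounded with genotype.

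Gata6 (ENSMUSG00000005836, mm9 chromosome 18, 11052508 to 11085633) was higher, not lower, in every library labelled Gata6-deleted. Its level was 2.76, 2.12, 2.62 and 2.45 rescaled FPKM in controls 1 to 4, with a mean of 2.49 ± 0.28 (SD, n = 4). Labelled libraries 1 to 4 had 4.81, 5.12, 4.90 and 4.12, with a mean of 4.74 ± 0.43 (SD, n = 4), a ratio of means of 1.90. The log2 fold change was 0.72 (SE 0.11), with a Benjamini-Hochberg adjusted p of 0.0443 in limma and an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries can give. Between 55.0 and 460.6 implied fragments stood behind each value. A gene-level FPKM takes in every annotated exon and does not resolve the floxed part, so these values did not check the deletion. The sign was positive in all 27 other settings tried, but the adjusted p stayed under 0.05 in only 5 of them. Because the groups did not overlap, only another scaling or a covariate could have turned that sign. Leaving out control 1, 2, 3 or 4 ended the call (adjusted p = 0.0877, 0.183, 0.162 and 0.124), as did leaving out labelled library 1, 2 or 3 (0.139, 0.0609 and 0.156). Without labelled library 4 it was kept (0.0321). Among the BKD titles the log2 fold change was 0.57 (adjusted p = 0.631), among the ASK and BSH titles 0.85 (adjusted p = 0.253), and with the prefix as a covariate 0.71 (adjusted p = 0.198).

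**Figure D1:**
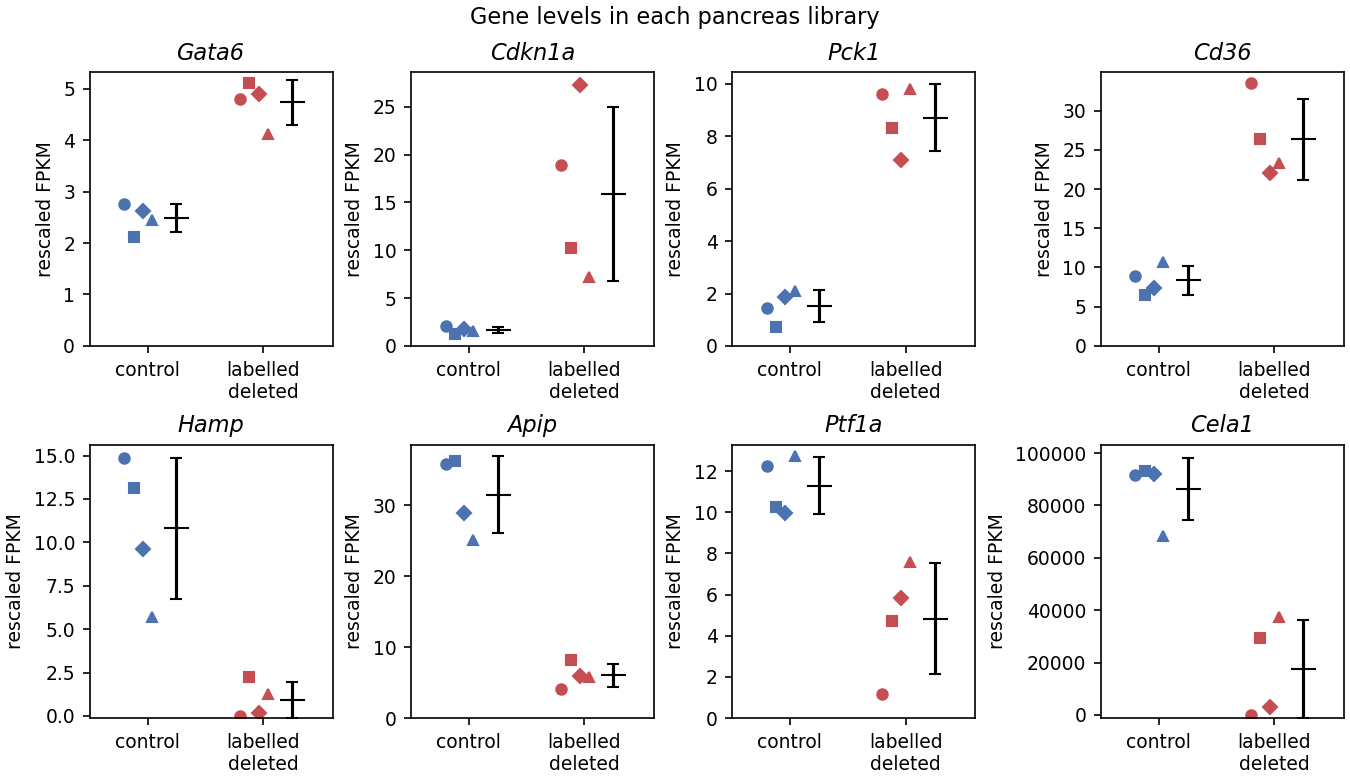
Rescaled FPKM of 8 genes in each control library (blue) and each library labelled Gata6-deleted (red), where circle, square, diamond and triangle mark libraries 1 to 4 of a group and the black line with bars is the mean ± SD (n = 4). Gata6 lies between 2.12 and 2.76 in the controls and between 4.12 and 5.12 in the labelled libraries, and Cela1 and Ptf1a are shown although they did not pass the test.

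The genes that rose in the labelled libraries included 4 members of the adipocyte list and 2 of the p53 list. Cdkn1a, the cell cycle inhibitor p21 and a p53 target, rose from 1.67 ± 0.36 in the controls to 15.9 ± 9.09 rescaled FPKM (mean ± SD, n = 4; log2 fold change 2.51, SE 0.36, adjusted p = 0.0363). Pck1, the gluconeogenic and glyceroneogenic enzyme, rose from 1.53 ± 0.61 to 8.71 ± 1.27 (log2 1.97, SE 0.20, adjusted p = 0.00852). Cidec, a lipid droplet protein, rose from 5.0 ± 2.36 to 20.9 ± 3.16 (log2 1.95, SE 0.29, adjusted p = 0.0363). Among the falls, Hamp, which encodes the iron hormone hepcidin, went from 10.8 ± 4.06 to 0.926 ± 1.06 (log2 -2.71, SE 0.42, adjusted p = 0.0443). Apip, an enzyme of methionine salvage, went from 31.5 ± 5.43 to 6.01 ± 1.64 (log2 -2.23, SE 0.21, adjusted p = 0.00713). Between 0 and 24.2 implied fragments stood behind each Hamp value, and between 6.81 and 48.0 behind each Apip value.

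The other large rises were those of Gdpd3 (log2 2.50), Tnfrsf12a, the receptor of the cytokine TWEAK (2.19), Mmd (1.89), the lipid droplet gene Plin4 (1.84), the p53 target Phlda3 (1.81), the fatty acid transporter Cd36 (1.55), Mrap (1.51), the peroxisomal transporter Abcd2 (1.51) and Prkar2b, a regulatory subunit of protein kinase A (1.49). The other large falls were those of the zinc transporter Slc39a11 (log2 -2.09), Azgp1 (-1.95), Pkd1l2 (-1.77), the iodotyrosine deiodinase Iyd (-1.73), the deubiquitinase Usp2 (-1.64), the oxysterol hydroxylase Cyp39a1 (-1.60), Hapln4 (-1.54), Fam132a (-1.53), the ribosomal protein gene Rpl29 (-1.40) and the fucosyltransferase Fut1 (-1.20). All 24 of these genes were picked for groups that did not overlap, so only another scaling or a covariate could have turned their sign. Each kept its sign in every setting that tested it. They passed the threshold in 8 to 23 of up to 28 other settings. With the prefix as a covariate none of the 24 passed in limma (adjusted p from 0.0592 to 0.214). The falls shrank under scaling to an equal sum outside the enzymes and to the implied fragment totals. Rpl29 went to -0.45 and -0.16, Fut1 to -0.53 and -0.29, Cyp39a1 to -0.77 and -0.50 and Fam132a to -0.69 and -0.41. The rises grew under the same scalings, for Cd36 to 2.45 and 2.71 and for Cidec to 2.81 and 3.05. Both scalings moved the median of all genes up, from 0.10 to 0.85 and 1.06. Under both scalings Xbp1, Gata4, Nr5a2, Atp5b, Cox4i1, Mbp, Plvap, Ccnd1, Insig1, Fdps, Anpep, Sox9, Pdx1 and Reg3b, named below with negative values, turned positive. Fold changes are on the log2(value + 1) scale, which understates the change of low genes such as Pkd1l2, at 2.69 ± 0.42 in the controls and 0.0768 ± 0.0751 in the labelled libraries (mean ± SD, n = 4).

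Of 11860 genes tested with limma, 26 rose and 23 fell at a Benjamini-Hochberg adjusted p under 0.05, and 37 of these 49 were protein-coding. At an unadjusted p under 0.05 there were 3570 genes (30.1%), 2120 higher and 1450 lower. The groups did not overlap in 2196 genes (18.5%), 1292 higher and 904 lower, where chance gives 2.86% on average over splits. Single splits can lie far from that average, since many genes move together. With control 4 and labelled library 4 exchanged, 1456 genes did not overlap, the most of any other split. The remaining protein-coding rises included the retinol carrier Rbp4 (log2 1.46). The falls included Srp54b (-1.07) and Srp54c (-0.92), near-identical genes of the signal recognition particle whose reads the counting could have split. These 3 were chosen after their values were seen. The count of 49 rested on the set of libraries: leaving out control 1, 2, 3 or 4 gave 26, 10, 10 and 26 genes, of which 15, 9, 10 and 18 were among the 49. Leaving out labelled library 1, 2, 3 or 4 gave 17, 97, 15 and 2566, of which 15, 35, 14 and 49 were among them. The BKD titles alone gave 0 higher and 16 lower, the ASK and BSH titles 89 higher and 2 lower (each with 1 library in a group, assumed to vary like the others). The prefix as a covariate gave 4 higher and 1 lower, and the fit without labelled libraries 1 and 3 gave 11 higher and 2 lower.

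Genes of acinar cells, which make and secrete the digestive enzymes, were lower in the labelled libraries, and by very different amounts in each. Elastase Cela1 ranged from 68300 to 93114 rescaled FPKM in the controls and was 131 in labelled library 1, 29364 in library 2, 2977 in library 3 and 37260 in library 4. Cela2a, Cel and Cpa1 had log2 fold changes of -3.90, -3.68 and -2.99. The list of digestive enzymes had a median log2 fold change of -2.94, with 22 of its 24 tested members negative and 16 lower without overlap. Its median per library was -6.45, -1.09, -3.25 and -0.67 in labelled libraries 1 to 4, against -0.33 to 0.33 in the controls. None of the 24 passed over all genes in limma and 0 passed adjusted over the list alone, with 10 at an unadjusted p under 0.05. The camera test of limma called the list lower (adjusted p = 7.54e-07), and the call was lost at adjusted p = 0.436 with an estimated correlation and under quantile normalization (median -1.38, adjusted p = 0.0754). The median was -3.89 among the BKD titles, -1.0 among the ASK and BSH titles and -0.86 without labelled libraries 1 and 3. Several members, such as the amylases and trypsins, are near-identical copies whose reads the counting could have split. Pnlip, Ctrb1, Amy2b and 5 other amylase genes lacked an estimate in at least 1 library and were not tested. Ctrb1 was 136516 and 114626 in controls 3 and 4 and 5853, 85891, 35403 and 103195 in labelled libraries 1 to 4. Pnlip was 67201 in control 3 and 90.9, 26750, 3579 and 31297 in the labelled libraries.

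**Figure D2:**
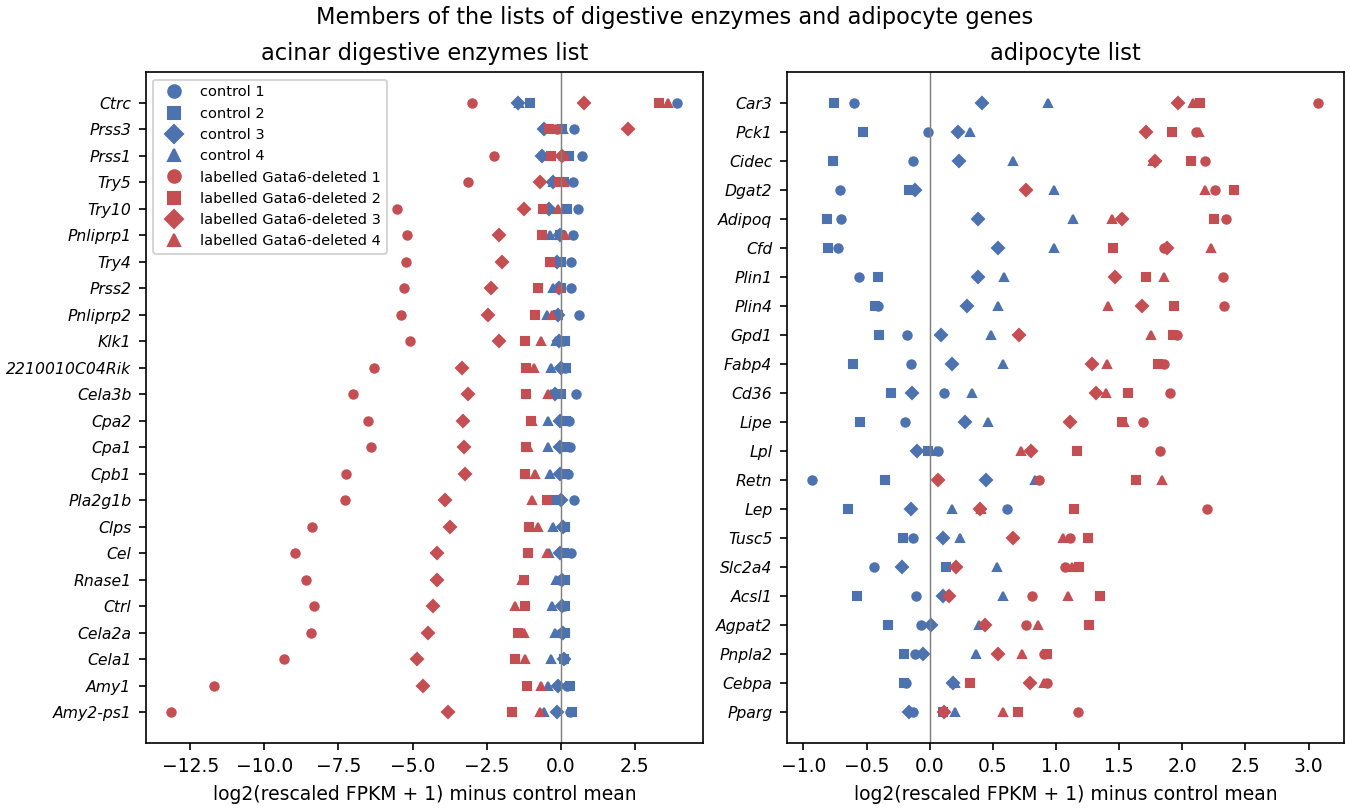
Each tested member of the digestive enzyme list (left) and of the adipocyte list (right) in each library, as log2(rescaled FPKM + 1) minus the mean of the controls, with controls in blue, libraries labelled Gata6-deleted in red and symbols for libraries 1 to 4. Most enzymes lie far below the controls in labelled libraries 1 and 3 and closer to them in libraries 2 and 4, and all 22 adipocyte genes have a positive mean change.

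Zymogen granule and secretion genes followed the enzymes, with a median of -1.67, 26 of 29 members negative, and Zg16 and Reg1 at log2 -3.59 and -2.25. Its median was -2.19 among the BKD titles, -0.76 among the ASK and BSH titles, -0.63 without labelled libraries 1 and 3, and -0.76 and -0.55 under equal-sum and implied-total scaling. None of the 29 passed over all genes and 0 adjusted over the list alone, with 21 at an unadjusted p under 0.05 in limma. The granule list was called lower by camera (adjusted p = 2.5e-07, but adjusted p = 0.436 with an estimated correlation). The acinar transcription factors were negative in 10 of 10 tested members, with a median of -0.69 that turned to 0.15 and 0.37 under the same scalings. Those scalings moved the median of all genes from 0.10 to 0.85 and 1.06. Here 0 of 10 passed over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05 in limma. The factors were called lower by camera (adjusted p = 0.000621, but adjusted p = 0.436 with an estimated correlation and 0.0762 without labelled libraries 1 and 3). Ptf1a, the regulator of acinar identity that also carries the Cre gene, was 11.3 ± 1.38 in the controls and 4.82 ± 2.70 in the labelled libraries (mean ± SD, n = 4; log2 -1.24, adjusted p = 0.114). Bhlha15, which encodes the secretory regulator MIST1, was 60.3 ± 10.5 in the controls (SD, n = 4) and 0.476, 36.9, 4.57 and 38.5 in labelled libraries 1 to 4. Rbpjl, Xbp1, Gata4 and Nr5a2 had log2 fold changes of -1.50, -0.70, -0.61 and -0.50, and none of them passed.

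Metabolic and protein-folding genes were also lower, most of all in labelled library 1, where the enzyme median was lowest. The amino acid and creatine metabolism list had a median of -1.05, with Gatm, the first enzyme of creatine synthesis, at log2 -1.99 and the asparagine synthetase Asns at -1.59. Its median turned to 0.17 under implied fragment totals, where that of all genes was 1.06. Of its 17 tested members 0 passed over all genes in limma (11 at an unadjusted p under 0.05), while 1 was higher and 10 lower adjusted over the list alone. Amino acid genes were called lower by camera (adjusted p = 1.34e-06, but adjusted p = 0.436 with an estimated correlation). Mitochondrial respiration genes had a median of -0.52 with all 24 negative, among them Atp5b (-0.77) and Cox4i1 (-0.67), and that median turned to 0.43 and 0.72 under the equal-sum and implied-total scalings, below the medians of all genes there. No member passed over all genes (0 of 24, 9 at an unadjusted p under 0.05) and 1 was lower adjusted over the list alone. Respiration genes were called lower by camera (adjusted p = 1.63e-07, but adjusted p = 0.436 with an estimated correlation and 0.217 under implied totals). Endoplasmic reticulum stress and folding genes had a median of -0.63, with the disulfide isomerase P4hb at -1.65, and it turned to 0.32 and 0.61 under the same scalings. Of 29 members 0 passed over all genes and 0 adjusted over the list alone (13 at an unadjusted p under 0.05). Folding genes were called lower by camera (adjusted p = 0.000621, but adjusted p = 0.436 with an estimated correlation and 0.0911 after quantile normalization). The medians in labelled libraries 1 to 4 were -2.23, -0.75, -1.03 and -0.45 for amino acid metabolism, -0.96, -0.47, -0.71 and -0.09 for respiration and -1.46, -0.25, -0.91 and 0.08 for folding. Within the BKD titles the medians of these 3 lists were -1.23, -0.76 and -0.90, and within the ASK and BSH titles -0.68, -0.44 and -0.17. Without labelled libraries 1 and 3 they were -0.51, -0.25 and -0.08.

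**Figure D3:**
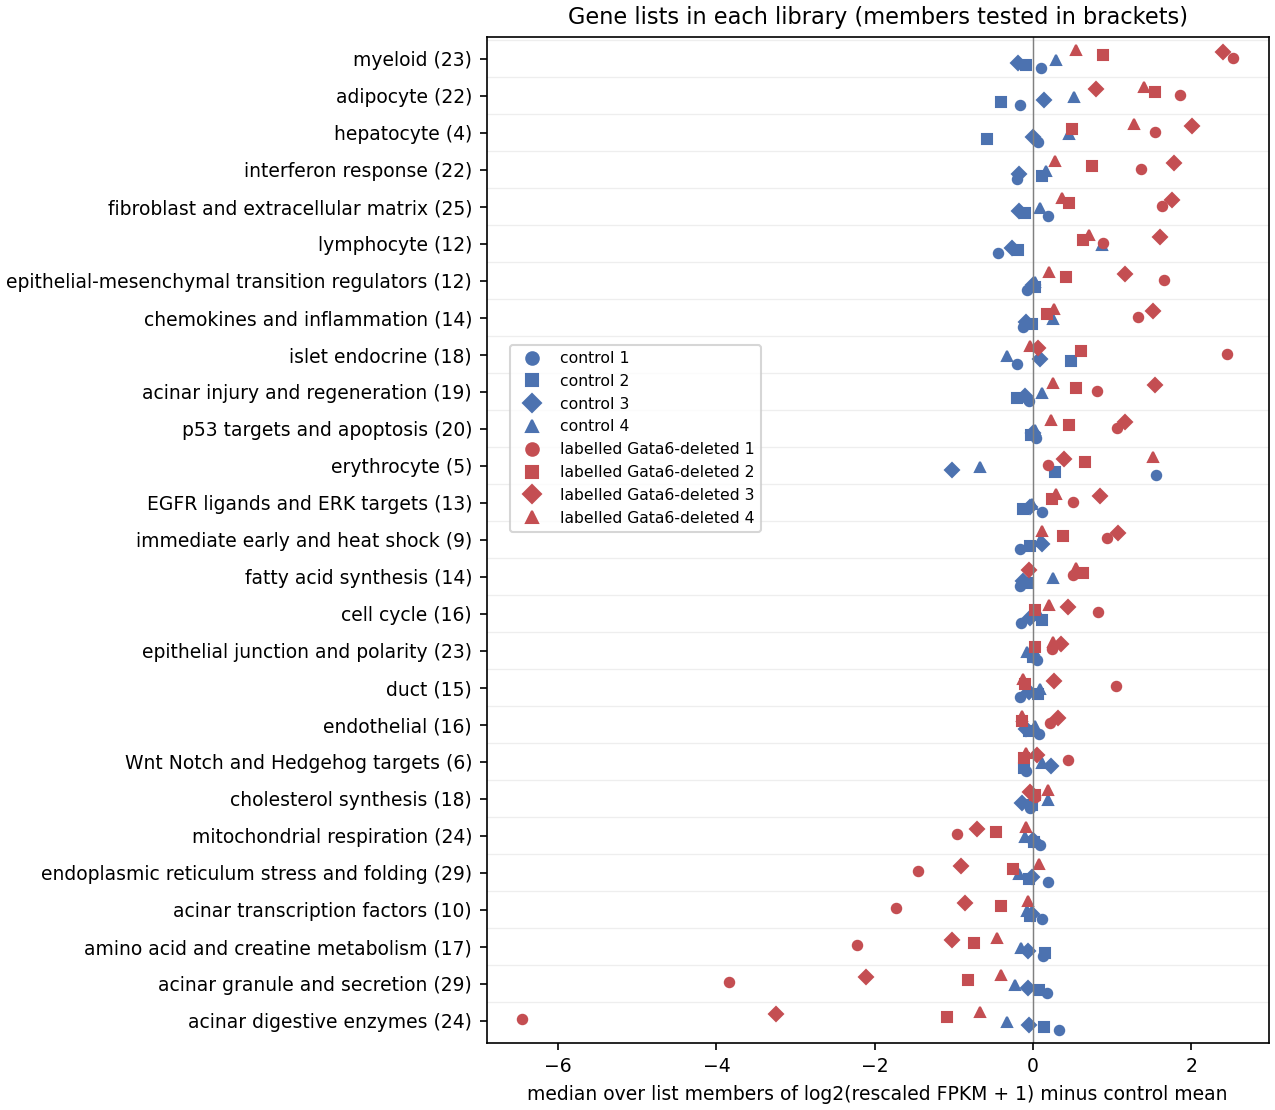
Median over the tested members of each of 27 gene lists, as log2(rescaled FPKM + 1) minus the mean of the controls, in each control (blue) and each library labelled Gata6-deleted (red), with symbols for libraries 1 to 4. Labelled libraries 1 and 3 lie farthest from the controls in the enzyme (-6.45 and -3.25) and myeloid (2.53 and 2.40) lists, whereas the adipocyte medians (1.85, 1.55, 0.80 and 1.41) follow another order; under the equal-sum and implied-total scalings the medians of the transcription factor, respiration and folding lists turn positive.

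Adipocyte genes were higher in all 4 labelled libraries. Their median was highest in labelled library 1 (1.85), which had the lowest enzymes, but smallest in library 3 (0.80), which had the next lowest. Pck1, Cidec, Plin4 and Cd36 rose, Cd36 from 8.37 ± 1.85 to 26.3 ± 5.14 (mean ± SD, n = 4). The adipocyte list had a median of 1.51, with 22 of 22 tested members positive, and 22, 22, 16 and 21 of them above every control in labelled libraries 1 to 4. In limma 4 of 22 passed over all genes and 21 adjusted over the list alone. Adipocyte genes were called higher by camera (adjusted p = 4.86e-12, but adjusted p = 0.436 with an estimated correlation). All 16 lists called shared this 0.436, and the unadjusted camera p of the adipocyte list at that setting, 0.072, was the lowest. The fry test, which asks only whether a list moves in 1 direction, gave 0.0269. The adipocyte median was 1.65 among the BKD titles, 1.40 among the ASK and BSH titles and 1.57 without labelled libraries 1 and 3. It was 2.36 and 2.58 under equal-sum and implied-total scaling, where the median of all genes was 0.85 and 1.06.

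Myeloid, fibroblast and lymphocyte genes were higher too, and labelled libraries 1 and 3 stood apart in the myeloid and fibroblast lists as they did in the enzymes. The myeloid list had a median of 1.64, and of 2.53, 0.88, 2.40 and 0.54 in labelled libraries 1 to 4, with the lysozyme gene Lyz2 at log2 1.59 and the complement gene C1qb at 1.91. None of its 23 tested members passed over all genes in limma (0 of 23, 21 at an unadjusted p under 0.05), but 21 did adjusted over the list alone. Myeloid genes were called higher by camera (adjusted p = 3e-07, but adjusted p = 0.436 with an estimated correlation). Fibroblast and extracellular matrix genes had a median of 0.98, with per-library medians of 1.63, 0.45, 1.76 and 0.37 and with Sparc at 1.39 and the proteoglycan Dcn at 0.97. Here 0 of 25 passed over all genes (21 at an unadjusted p under 0.05) and 20 adjusted over the list alone. Fibroblast genes were called higher by camera (adjusted p = 3e-07, but adjusted p = 0.436 with an estimated correlation). The lymphocyte list had a median of 0.94, with Ighm at 0.70 and Cd52 at 1.62, but control 4, at 0.88, reached the labelled libraries (0.89, 0.63, 1.6 and 0.71). Of its 12 members 0 passed over all genes (9 at an unadjusted p under 0.05) and 7 adjusted over the list alone. Lymphocyte genes were called higher by camera (adjusted p = 0.000452, but adjusted p = 0.436 with an estimated correlation and 0.0904 among the ASK and BSH titles). Among the BKD titles the medians of the myeloid, fibroblast and lymphocyte lists were 1.85, 1.06 and 1.47, and among the ASK and BSH titles 0.93, 0.48 and 0.48. Without labelled libraries 1 and 3 they were 0.73, 0.34 and 0.66. Under equal-sum scaling they were 2.48, 1.94 and 1.62, and under implied totals 2.71, 2.23 and 1.74.

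Markers of other cell types gave no call by the test chosen beforehand, though some did in other settings. Endothelial genes had a median of 0.10, with a negative direction in camera (adjusted p = 0.736), that was -0.04 after quantile normalization but 0.85 and 1.07 under equal-sum and implied-total scaling. It was -0.07 among the BKD titles and -0.13 among the ASK and BSH titles. Over all 8 libraries Plvap was at -0.16 and Cd34 at 0.49. In limma 0 of 16 passed over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. Islet endocrine genes had a median of 0.76 (adjusted p = 0.0898), which reached 2.45 in labelled library 1, where Ins2 was 4366 against 445 to 1169 in the controls. Of its members 0 of 18 passed over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. The islet list was called without control 2 (adjusted p = 0.0407) or labelled library 3 (0.00745) and among the ASK and BSH titles (0.0238). With all 8 libraries it was called under median-ratio scaling (0.0465), quantile normalization (0.0338) and a minimum mean of 5 (0.0322). Duct genes had a median of 0.20 (adjusted p = 0.354), which was -0.16 among the ASK and BSH titles, with Clu at 1.43, Krt19 at 1.13, Muc1 at -1.75 and the transcription factor Sox9 at -0.07. In limma 0 of 15 passed over all genes (4 at an unadjusted p under 0.05) and 2 adjusted over the list alone. Erythrocyte genes had a median of 0.70 (adjusted p = 0.61), which was -0.78 among the BKD titles, with Hbb-b1 at 0.54 and Hba-a1 at 1.01. In limma 0 of 5 passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05. Hepatocyte markers had 4 tested members and a median of 1.33 (camera adjusted p = 0.108, fry 0.0269), with the acute phase gene Hp at 2.93 and Trf at 1.48. Of these 4, 0 passed over all genes (3 at an unadjusted p under 0.05) and 3 adjusted over the list alone. The hepatocyte list was called under quantile normalization (0.035), a minimum mean of 5 (0.0322) and among the BKD titles (0.0261).

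Stress, signalling and inflammatory groups were higher, each with larger medians in labelled libraries 1 and 3 than in 2 and 4. The list of p53 targets and apoptosis genes had a median of 0.72, and all 20 members were positive. Cdkn1a and Phlda3 passed over all genes, and Cdkn1a was at 18.9, 10.2, 27.3 and 7.16 rescaled FPKM in labelled libraries 1 to 4. Adjusted over the list alone 9 passed. The p53 list was called higher by camera (adjusted p = 1.69e-06, but adjusted p = 0.436 with an estimated correlation). Interferon response genes had a median of 1.01, with the class I histocompatibility genes H2-K1 and H2-D1 at 1.29 and 0.79. In limma 0 of 22 passed over all genes (18 at an unadjusted p under 0.05) and 18 adjusted over the list alone. Interferon genes were called higher by camera (adjusted p = 3.16e-07, but adjusted p = 0.436 with an estimated correlation). Regulators of epithelial-mesenchymal transition had a median of 0.85, with the matrix metalloprotease Mmp14 at 1.58 and Tgfb1 at 1.27. There 0 of 12 passed over all genes (8 at an unadjusted p under 0.05) and 8 adjusted over the list alone. Transition regulators were called higher by camera (adjusted p = 0.000665, but adjusted p = 0.436 with an estimated correlation and 0.0768 under implied totals). Per-library medians in labelled libraries 1 to 4 were 1.06, 0.46, 1.16 and 0.22 for the p53 list, 1.37, 0.75, 1.79 and 0.27 for the interferon list and 1.66, 0.42, 1.16 and 0.20 for the transition list. Within the BKD titles the 3 medians were 0.84, 1.38 and 1.18, and within the ASK and BSH titles 0.47, 0.65 and 0.39. Without labelled libraries 1 and 3 they were 0.33, 0.54 and 0.32. Labelled libraries 1 and 3 also had the highest myeloid (2.53 and 2.40) and fibroblast (1.63 and 1.76) medians, and whole tissue did not separate a change of cell mix from a change within cells.

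Chemokine and inflammation genes had a median of 0.84 (labelled libraries 1.33, 0.18, 1.51 and 0.27), with complement C3 at 1.63 and Saa3 at 0.14. None of 14 passed over all genes (0, with 5 at an unadjusted p under 0.05 in limma) and 4 adjusted over the list alone. Chemokine genes were called higher by camera (adjusted p = 0.0015, but adjusted p = 0.436 with an estimated correlation and 0.0793 under implied totals). Within the ASK and BSH titles their median was 0.09 (adjusted p = 0.281) and within the BKD titles 1.31. Ligands of the EGF receptor and targets of ERK had a median of 0.65 (labelled libraries 0.50, 0.24, 0.84 and 0.28), with Egf itself at -2.09 and the ERK target Etv5 at 1.29. Of its 13 members 0 passed over all genes (8 at an unadjusted p under 0.05), and 7 were higher and 1 lower adjusted over the list alone. This list was called higher by camera (adjusted p = 0.0155) and fry (0.0269), but had adjusted p = 0.436 with an estimated correlation and 0.0507 without labelled library 4. It also lost the call under equal-sum scaling (0.0834), under implied totals (0.223) and among the ASK and BSH titles (0.0598). Immediate early and heat shock genes, which handling of the tissue can induce, had a median of 0.62 (labelled libraries 0.94, 0.38, 1.08 and 0.12), with Jun at 0.94 and Ier2 at 0.00. Here 0 of 9 passed over all genes (5 at an unadjusted p under 0.05) and 4 adjusted over the list alone. Immediate early genes were called higher by camera (adjusted p = 0.0139, but adjusted p = 0.436 with an estimated correlation and 0.0768 under implied totals). Among the BKD titles the medians of the EGF receptor and immediate early lists were 0.60 and 0.85, and among the ASK and BSH titles 0.21 and 0.42. Without labelled libraries 1 and 3 the chemokine, EGF receptor and immediate early medians were 0.20, 0.24 and 0.30.

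The remaining lists gave no call by the test chosen beforehand, though 4 of them did in other settings, and none of their members passed over all genes in limma. Acinar injury and regeneration genes had a median of 0.74 (adjusted p = 0.172; 0 of 19 adjusted over the list alone, 7 at an unadjusted p under 0.05), with Reg2 at -1.32, Reg3b at -0.55 and Pdx1 at -0.37. Control 4 stood apart from the other controls in Reg2 and Reg3b, at 21236 and 6584. Reg2 was at 0.36 among the ASK and BSH titles, and Reg3b was at 0.29 after quantile normalization. The list was called under quantile normalization (0.00811) and a minimum mean of 5 (0.0159). Epithelial junction and polarity genes had a median of 0.21 (adjusted p = 0.0697), with keratins Krt8 at 0.83 and Krt18 at 0.36. It was called without labelled library 1 (0.0293) or libraries 1 and 3 (0.0421), with no minimum (0.0287) or one of 5 (0.0115), under equal-sum scaling (0.0425) and with sample weights (0.04997). In limma 0 of 23 passed over all genes (8 at an unadjusted p under 0.05) and 6 adjusted over the list alone. Cell cycle genes had a median of 0.41 (adjusted p = 0.089), with Pcna at 0.23 and Ccnd1 at -0.32. They were called without labelled library 2 (0.0239), with no minimum (0.0031), among the BKD titles (0.00549) and on the deposited scale (0.00406). For them 0 of 16 passed over all genes or adjusted over the list alone (6 at an unadjusted p under 0.05). Fatty acid synthesis genes had a median of 0.47 (adjusted p = 0.295), with Scd1 at 1.72 and Fasn at 1.13. The call appeared without labelled library 3 (0.0187) or libraries 1 and 3 (0.000932), among the ASK and BSH titles (0.0388) and with a minimum of 5 (0.0342). It also appeared with the prefix (0.0345) or Xist (0.0398) as a covariate and under implied totals (0.0164). Here 0 of 14 passed over all genes (6 at an unadjusted p under 0.05), with 3 higher and 1 lower adjusted over the list alone. Cholesterol synthesis genes had a median of 0.00 that was negative under 2 other scalings (adjusted p = 0.983), with Insig1 at -0.79 and Fdps at -0.30. Of these 18 genes 0 passed over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05. Wnt, Notch and Hedgehog targets had a median of 0.07 that was likewise negative under 2 other scalings and in camera's direction (adjusted p = 0.761), with Hes1 at 0.12 and Ptch1 at 0.01. Hes1 was at -0.66 among the ASK and BSH titles and Ptch1 at -0.19. Of these 6 genes 0 passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05.

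Another 4 lists had fewer than 4 tested members and no list test, and 0 of their members passed over all genes in limma. Of the nerve and glia genes, Pmp22 was at log2 0.99 and Mbp at -0.36, both passing adjusted over the list alone (adjusted p = 0.0022 and 0.0424), though Mbp was at 0.45 and 0.70 under equal-sum and implied-total scaling. Of the gastric and intestinal genes, Gkn3, Pgc and Anpep were at 2.36, 1.88 and -0.42, and 0 of 3 passed adjusted over the list alone (lowest adjusted p = 0.0552, 1 at an unadjusted p under 0.05). Pgc, the pepsinogen C gene of the stomach, reached 113.6 in labelled library 2, against 0 to 2.48 in the other 7 libraries. The skeletal muscle gene Mylpf was at -0.75 (adjusted over the list alone 0.237). The sex-linked genes Eif2s3y, Ddx3y and Xist were at 1.77, 1.07 and -2.14 (0 of 3 adjusted over the list alone, lowest adjusted p = 0.173), and followed the title prefix and not the genotype.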

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

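The tests of explanations for the enzyme, Gata6 and adipocyte patterns were chosen after the results were seen. In 244 groups of 4 libraries, 1 library lay far from the other 3 in 17, where chance gives about 1 in 20 groups, or 12.2. Examined in each group were the tested named genes, the list medians, and the implied fragments, genes above 0, summed FPKM and its enzyme share. All 17 were values of single genes. Of the 17, 10 were in labelled libraries, 5 of them in labelled library 1, and 7 in controls.

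Labelled library 1 had the islet genes Ins2 at 4366 rescaled FPKM (others of its group 595 to 1180) and Ins1 at 688.5 (69.1 to 126.5). It also had Ccnd1 at 10.4 (2.31 to 3.5), Ptch1 at 3.04 (1.38 to 1.59) and Prkar2b at 6.27 (3.65 to 4.03). Labelled library 2 had the stomach gene Pgc at 113.6 (0.088 to 2.48) and Xist at 32.0 (0 to 0.0093). Labelled library 3 had Clu at 1985 (807 to 871). Labelled library 4 had Fdps at 8.89 (3.35 to 3.96) and Hbb-b1 at 125 (46.5 to 53.8). Control 4 had Reg2 at 21236 (5965 to 7962), Reg3b at 6584 (404 to 1056), Fasn at 25.2 (9.80 to 12.02) and Cela1 at 68300 (91578 to 93114). Control 1 had Eif2s3y at 5.34 (0 to 0.281), Nr5a2 at 5.94 (4.53 to 4.67) and Mmp14 at 3.04 (2.55 to 2.63).

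The digestive enzyme genes were far lower in labelled libraries 1 and 3 than in 2 and 4. Library depth was examined by the number of genes above 0. It was 23024 and 22715 in labelled libraries 1 and 3, against 18345 to 19729 in the controls. That number cannot decide, since reads no longer taken up by enzymes would also raise it. Implied fragments summed to 5325492 and 8957747 in these libraries, against 6731314 to 7917966 in the controls, without the genes that lack an estimate. The 2 libraries thus did not share a lower total. A lower depth alone would not move whole lists in opposite directions. In labelled library 1, 23 of 24 tested enzymes lay below every control, and 25 of 25 fibroblast genes lay above every control. In labelled library 3, 21 of 24 enzymes lay below and 1 above, and again 25 of 25 fibroblast genes above. For the genes of these lists, these values argue against depth as the cause in either library. A lower share of acinar cells alone would raise the markers of all other cells alike, but the myeloid list median exceeded the endothelial one by at least 2.09 in these 2 libraries, where the controls spanned 0.37. Title prefix or sex was not the whole cause, because the enzyme median of the lower of the other BKD libraries was -0.67, where the controls spanned 0.66. A stronger effect of the labelled genotype in some animals, or damage to the tissue of these 2 animals, may account for the difference and was not tested.

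Gata6 was higher in all 4 libraries labelled Gata6-deleted, which is unlikely to come from the scaling of the values, since the lowest log2 fold change over 4 other scalings was 0.57 (SE 0.12), although its adjusted p missed 0.05 under all 4. Cells that gain with the acinar loss stay open as a source, because the range of Gata6 over the labelled libraries depended on the scaling. It was 0.26 (log2) against 1.39 for the fibroblast list. Under median-ratio scaling it was 0.33 against 1.25 and under quantile normalization 0.32 against 1.85. Under equal-sum scaling it was 1.75 against 3.10 and under implied fragment totals 2.09 against 3.53. Group labels exchanged between all libraries remain open. The Gata6 levels of all 8 libraries lie on the side opposite to a loss, but at gene level they cannot decide. Under such an exchange the lower enzyme medians (-6.45, -1.09, -3.25 and -0.67 in labelled libraries 1 to 4) would belong to mice with the Cre gene alone. Whether the Cre gene alone could lower them was not tested. A transcript that lacks the floxed part but is still made, at a higher level, is another biological explanation. The Gata6 values could not test it, because they do not resolve exons.

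Adipocyte genes were higher in all 4 labelled libraries. More fat tissue or fat cells in the sample, inside the pancreas or brought along in dissection, stays open: that 22 of 22 tested members were positive restates the pattern and decides nothing. A lower share of acinar cells alone is unlikely as the whole cause, since the adipocyte median exceeded the endothelial one by 1.34 on average over the labelled libraries (highest control 0.49, control SD 0.40), although labelled library 3 alone, at 0.49, lay within the control range. The BKD prefix or sex is argued against as the whole cause, as the adipocyte median was 1.57 with the prefix as a covariate and 1.53 with Xist (control SD 0.40). Prefix ASK against BSH separates only controls 2 to 4 from labelled library 2, and stays open for that library. Labelled libraries 1, 3 and 4 share the BKD prefix with control 1, and the adipocyte median among the BKD titles was 1.65. The genotype as labelled stays open, untested.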

How the results depend on the processing

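Of the alternatives here, the deposited scale, the HIDATA genes at 0, protein-coding genes only, the fit without labelled libraries 1 and 3, the ASK and BSH titles, the prefix covariate and the implied fragment totals were chosen after seeing the data, as was the test of other splits for the count of genes; the test for lists was written beforehand. The 49 genes (26 higher, 23 lower) were matched or exceeded in 1 of the 35 splits of the 8 libraries, the real one. The highest other split gave 5. A share of 1 in 35 is the smallest that these splits can give, and the test was chosen after the count was seen. It makes chance less likely but does not exclude it. The 16 list calls were matched or exceeded in 6 of 35 splits, with 19 in the highest other. That split kept labelled libraries 1 and 3 on the same side, so it still held the shift that these 2 share. The number of list calls therefore cannot decide, and chance is not excluded for them. Only the adipocyte list had its median compared over splits. Its size was 1.51 in the real split and at most 1.19 in any other. With an estimated correlation 0 lists were called in each of the 35 splits. The adjusted camera p of 0.436 at that setting was shared by all 16 lists called. Their unadjusted camera p ran from 0.072 (adipocyte) to 0.2745 (transition regulators).

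The counts stayed within 1.5 times of 26 and 23 for both directions with pseudocount 0.1, median-ratio scaling, no trend, robust variances, good status only and the HIDATA genes at 0. The higher genes were 14 with pseudocount 5, 12 with quantile normalization, 2316 with sample weights, 6 with the Xist covariate, 0 in the BKD titles (615 genes at an unadjusted p under 0.05 in limma), 57 on the deposited scale, 62 among protein-coding genes, 11 without labelled libraries 1 and 3, 89 in the ASK and BSH titles, 4 with the prefix covariate and 5 with implied totals. The lower genes were 11 with no expression filter, 15 with a mean of at least 5, 0 with an equal sum outside the enzymes (5128 at an unadjusted p under 0.05), 1478 with sample weights, 4 with the Xist covariate, 46 among protein-coding genes, 2 without labelled libraries 1 and 3, 2 in the ASK and BSH titles, 1 with the prefix covariate and 0 with implied totals (5851 at an unadjusted p under 0.05). Leaving out 1 library gave 7 to 1366 higher and 3 to 1200 lower: in total 26, 10, 10 and 26 without controls 1 to 4 and 17, 97, 15 and 2566 without labelled libraries 1 to 4. Of all calls 53.1% were higher, against 40% after quantile normalization, 36.8% with pseudocount 5 and 100% under equal-sum and implied-total scaling, which move the median of all genes from 0.10 to 0.85 and 1.06. Every one of the 49 that was tested kept its sign in each setting, except under equal sum (48 of 49) and implied totals (42 of 49). Fewer samples were left in the fits of a title set or without a library, yet the counts rose without labelled library 2 or 4. Labelled library 4 had a Pearson r of 0.88 to 0.92 with the controls. With labelled libraries 1, 2 and 3 it had 0.71, 0.87 and 0.84. Whether this likeness to the controls lowered the count of 49 was not tested, nor were other causes.

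Gata6 kept its positive sign throughout (0.72, adjusted p = 0.0443) but missed the threshold with pseudocount 0.1 (0.90) and 5 (0.38), no filter (0.72), median-ratio (0.63), quantile (0.57), equal-sum (1.5) and implied-total (1.71) scaling, no trend (0.72), robust variances (0.72), the Xist covariate (0.71), the BKD titles (0.57), the ASK and BSH titles (0.85), the prefix covariate (0.71), the deposited scale (0.93), without labelled libraries 1 and 3 (0.69) and in 7 of 8 fits without 1 library (0.67 to 0.77 over the 8), at adjusted p from 0.0540 to 0.631. Gata6 fell under the stricter minimum of 5 and was not tested there. Of the 16 list calls 0 held with an estimated correlation and 2 with fry (adipocyte and EGF receptor lists), which also called the hepatocyte list. The erythrocyte list reversed in the BKD titles, to a median of -0.78 (adjusted p = 0.0261); over all settings the cause was not tested. Low genes carry counting error, 1 fragment being worth a median of 0.0365 to 0.0959 rescaled units per sample in genes that implied 1. The worth differs by gene, and Hamp and Apip rested on at most 24.2 and 48.0 implied fragments. No paired analysis was possible because replicate numbers only follow the order of the records.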

Other observations

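The tests on short features and on genes named here were chosen after the results were seen; the test on chromosome positions with nearby loci merged was written beforehand, and the one without merging was added later. The chymotrypsin C gene Ctrc, chosen after its values were seen, was, with Prss3, 1 of the 2 tested digestive enzymes with a positive log2 fold change (1.18 and 0.40): it was 11549 rescaled FPKM in control 1 but 364, 274 and 280 in controls 2 to 4, and 93.7, 7481, 1301 and 9231 in labelled libraries 1 to 4. Its locus (mm9 chromosome 4, 141394154 to 141402274) overlaps that of 1810035I16Rik (141400236 to 141402905), an antisense RNA gene that fell (log2 -2.42, limma adjusted p = 0.0363), from 4.17, 8.89, 7.06 and 10.8 in controls 1 to 4 to 0.604, 1.84, 0.304 and 0. The sources used here do not say whether counting used strand, and the values of both genes are uncertain.

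In the stomach genes, labelled library 2 held Pgc at 113.6 and Gkn3 at 56.3 rescaled FPKM, against at most 2.48 and 5.01 in the other 7 libraries. Labelled library 1, where the enzymes were lowest, had the highest islet median (2.45) and duct median (1.05).

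Of the 49 genes that passed (26, 10, 10 and 26 without controls 1 to 4, and 17, 97, 15 and 2566 without labelled libraries 1 to 4), segments of chromosome from another strain that differ between the groups could explain some, since the mice were of mixed background. Many such genes would lie close together, but counting loci within 500 kb once left 45, with 2 pairs within 5 Mb, where 2000 random sets of tested genes had a median of 4 and 94.9% had as many. Without merging there were 7 pairs, against a median of 6, and 49.75% of random sets had as many. Of the 7, 4 were among the Srp54 copies or an overlapping pair, and 1 was Rpl29 and Pcbp4, whose starts lie 24403 bases apart. Single genes in such segments are not excluded. Around Gata6 itself, 50 genes within 10 Mb were tested, and 0 passed in limma. Of the 50, 7 (14%) had groups that did not overlap, against 18.5% of all genes and 2.86% by chance on average over splits.

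Another 5 features were listed at 0 in all 4 controls and above 0.5 in all 4 labelled libraries, and 0 features the other way round. They were Snora34, Mir692-1, Gm13800, AC153147.2 and AC102440.1, named after their values were seen, each spanning 60 to 166 bases and resting on at most 9.72 implied fragments; the first 3 passed (limma adjusted p = 6.21e-06, 0.000138 and 0.0108). Copies that share reads stay open as a source: 0 of the 5 were listed as protein-coding, but only 2 had a biotype. AL645948.1, which also passed (adjusted p = 0.000211), overlaps the passing pseudogene Gm12164 on chromosome 11.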
